A study of Rattus norvegicus with 4 samples.

How the data were processed

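Total RNA from RTEC11 cells was hybridised to an Affymetrix rat expression array, 1 array per sample. Per the labels' protocols, RNA was treated with DNase, double-stranded cDNA was made from 5 µg of total RNA, and biotin-labelled cRNA was transcribed from it and stained with phycoerythrin. The deposited values are intensities on a linear scale, 1 per probe set and array, for 15923 probe sets. The software that summarised the probes into these intensities is not given in the sources used here, and the table used here carries no detection calls. From the values, the authors' intensities have a mean of 500 on each array once 2% of the probe sets is trimmed at each end, so the arrays had been scaled before deposit. Median intensities were 152.7 and 155.6 on the permissive arrays and 174.3 and 171.1 on the nonpermissive ones. Of the values, 0.207% were identical between the 2 permissive arrays and 0.220% between the 2 nonpermissive arrays, so no array was counted as a copy of another.

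Groups and replicate numbers came from the sample titles. The design, the gene lists, the rule for the named genes and all alternatives other than the 2 named as added were fixed before the data were examined. Intensities were taken as log2(intensity + 16), so a log2 or fold change is on that scale and understates the change of dim genes. The array medians differed by 0.174 on the log2 scale, above the limit of 0.1 set for using values without further normalization, so the 4 arrays were quantile normalized after the 57 control probe sets had been left out. Probe sets were named through GEO's platform annotation, with symbols checked by Entrez identifier against the RefSeq gene table of assembly GRCr8, in which 12754 matched and 0 symbols changed. Of 15866 other probe sets, 12783 had 1 gene symbol, 312 had several and 2771 had none listed. Probe sets with several genes were not used. Each of 10412 genes was represented by its probe set with the highest mean over the 4 arrays, with those ending in _x_at taken only where there was no other. Where a gene had further tested probe sets these could disagree: of 988 such genes, 30 had probe sets called in opposite directions. Among the 30 are Tpm1 and Id2, counted as higher in the smooth muscle and TGF-beta lists below, and the antioxidant list gene Tkt. Of 24 further probe sets above the dim limit that belong to named genes that were called, 23 had the sign of the one used. Genes with a mean under the 40th percentile of all probe sets, a log2 value of 6.60 or an intensity of 81.1, were left out as dim, which removed 3396 and left 7016.

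Nonpermissive arrays were compared with permissive arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, 2 residual degrees of freedom and a median of 9.23 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Gene lists, 30 in all with 827 genes, of which 609 had a probe set and 471 were tested, covered the cell cycle, p53 targets, growth and metabolism, stress, airway cell types, and other cell types that a culture could hold. The 25 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Named genes were the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, leaving out uncharacterised loci, the 2 called members of each list with the largest rise and the 2 with the largest fall (or the largest change where none was called), and a fixed set of cell cycle, airway, stress and mesenchymal genes. Hspa1b and Hsp90aa1 of that set had no probe set of their own. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

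The procedure was tested on simulated data made from the spread of these arrays, with changes planted in known genes at least 1 log2 unit above the dim limit. In the simulated comparison of 7015 genes, 58.2% of 67 genes changed by 0.5 on the log2 scale were recovered, 95.5% of 67 changed by 1 and 97.0% of 66 changed by 2, and 9 unchanged genes were among the 176 called. The list test called the planted list and 0 of the other lists. The simulated noise was drawn independently for each gene, so it cannot show false list calls from correlated genes. Few genes were changed, with rises and falls in equal numbers, so normalization under a wide or one-sided response was not tested. The alternatives were the deposited scale, centring on the median, adding 1 or 64 in place of 16, no filter or the 60th percentile for dim genes, the mean of a gene's probe sets, all probe sets, no intensity trend, the replicate number as a block, and leaving out each array in turn. Chosen after seeing the data were the alternative without genes represented by a probe set ending in _x_at or _s_at and the alternative in which each array was scaled to the mean log2 value of its 24 poly-A spike-in control probe sets. No genome coordinates were used.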

Results

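Gene expression was measured in RTEC11, a rat tracheal epithelial cell line. RTEC11 cells carry a temperature-sensitive form of the simian virus 40 large T antigen, a viral protein that binds p53 and the retinoblastoma proteins and keeps cells dividing. The antigen is active at the permissive temperature of 33 °C and loses its activity at the nonpermissive temperature of 39 °C. Cells were kept for 3 days at either temperature, and 2 arrays were run per temperature, 4 in all. The labels name growth arrest and differentiation at the nonpermissive temperature as the subject of the study. Because the temperature and the activity of the antigen changed together, no difference given here can be assigned to either of them. The values are probe set intensities that had been scaled to a trimmed mean of 500 on each array. Replicates correlated at 0.978 at 33 °C and 0.981 at 39 °C over the 15866 probe sets that are not controls, against 0.951 to 0.953 between temperatures. The number of arrays limits the precision. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

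The cells at 39 °C differed from those at 33 °C in 3448 of 7016 genes tested (limma, adjusted p under 0.05), of which 1619 were higher and 1829 lower. With 16 added to each intensity, the largest rise with both arrays on one side was that of Mgmt, a DNA repair protein that removes alkyl groups from guanine, from a log2 intensity of 6.46 ± 0.42 to 11.75 ± 0.21 (SD, n = 2 each). This was a 39.2-fold rise with an adjusted p of 9.40e-09. Rbp2, a cellular retinol-binding protein, rose 35.3-fold, Ephx1, the microsomal epoxide hydrolase, 27.8-fold, and Penk, which encodes the enkephalin precursor, 16.3-fold. Selenop, a secreted selenium transport protein, rose 35.5-fold, with a log2 change of 5.85 without permissive replicate 1 and 4.44 without permissive replicate 2. A second Selenop probe set, below the limit for dim genes, had a log2 change of -0.61. The keratins Krt4 and Krt6c rose 16.6-fold and 12.1-fold, and a second Krt6c probe set had a log2 change of 3.01 against 3.60. Further large rises were those of Ccdc80 (13.9-fold), Spetex2l2 (10.3-fold), the cyclin Ccnd2 (9.98-fold), Smpdl3a (9.26-fold) and RT1-CE5 (22.1-fold). RT1-CE5 belongs to the class I histocompatibility genes, whose members are so alike that its probe sets may detect several of them. Its other probe sets above the limit for dim genes had log2 changes of 2.03, 1.89 and 3.49, against 4.46 for the one used. At 33 °C the level of Mgmt, Selenop, Rbp2, Krt4, Penk, Spetex2l2, Smpdl3a and RT1-CE5 lay under the limit for dim genes, so their fold changes and their order depend on the 16 added to each intensity.

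The largest fall was that of Rbm3, an RNA-binding protein induced by cold, from 13.59 ± 0.20 to 10.39 ± 0.15 (SD, n = 2 each), 9.22-fold lower at 39 °C with an adjusted p of 9.40e-09. Slc7a5, which carries leucine and other large neutral amino acids into cells, was 8.08-fold lower. The kallikrein protease Klk6 was 6.89-fold lower, uridine phosphorylase Upp1 6.69-fold, the thrombin receptor family member F2rl2 6.64-fold and the metallothionein Mt2A 6.30-fold. Falls between 4.64-fold and 5.75-fold were found for the chaperonin subunit Cct8, the iron-binding protein Lcn2, Npw, Nipal1 and the transferrin receptor Tfrc. The levels of Klk6, Upp1, F2rl2, Mt2A, Uchl1, Lcn2, Npw and Nipal1 at 39 °C lay under the limit for dim genes. Uchl1, a ubiquitin hydrolase, had a log2 change of -2.56, which was -1.81 without nonpermissive replicate 1 and -3.32 without nonpermissive replicate 2. In all, 764 genes changed at least 2-fold, 432 up and 332 down, and 62 rose and 19 fell at least 4-fold. The groups did not overlap in 75.1% of the tested genes, where chance gives 33.3%. The balance of rises and falls depended on how the arrays were scaled. The share of calls that were higher was 47.0% after quantile normalization, 52.3% on the deposited scale, 36.7% with each array centred on its median and 19.2% with each array scaled to its poly-A spike-in controls. The median log2 change of all genes tested was -0.04, 0.02, -0.13 and -0.36 under these scalings in the same order.

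**Figure D1:**
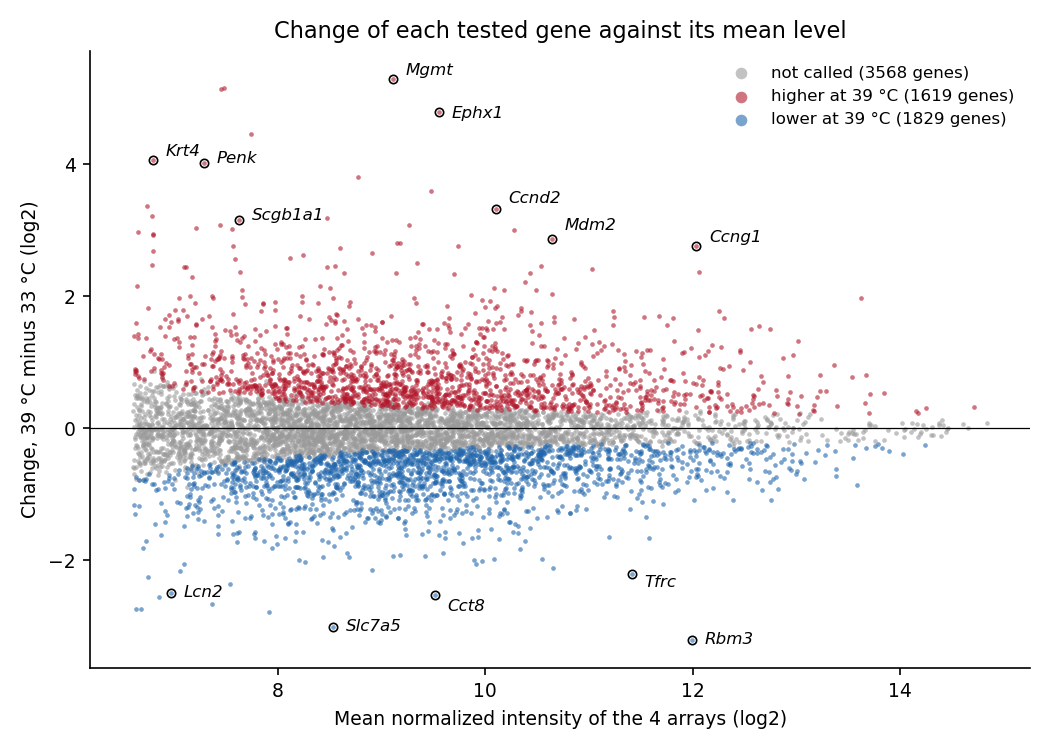
Each point is 1 of the 7016 tested genes, placed by its mean log2 normalized intensity over the 4 arrays (horizontal axis) and its log2 change at 39 °C against 33 °C (vertical axis). Colours mark the 1619 genes called higher, the 1829 called lower and those not called, and the circled genes include Mgmt at 5.29 and Rbm3 at -3.20.

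Targets of p53, the transcription factor that large T antigen binds, rose together. Of 18 tested, 13 rose and 2 fell, with a median log2 change of 1.10 and an adjusted p of 2.27e-06 by camera, limma's test of a list against all other genes. The adjusted p was 0.257 with an estimated correlation. Besides Ephx1, these were led by Mdm2, the ubiquitin ligase that degrades p53, which rose by 2.87 ± 0.12 (SE) on the log2 scale, from 9.21 ± 0.19 to 12.08 ± 0.14 (SD, n = 2 each). Ccng1, a cyclin-like p53 target, rose by 2.75 ± 0.12 (SE). The kinase inhibitor Cdkn1a (p21) rose by 2.51 ± 0.19 (SE). Its second probe set rose less, with a log2 change of 0.43. Epha2 and Cd82 were the members that fell, with log2 changes of -0.73 and -0.57, and the Cd82 call was lost without permissive replicate 2 (log2 change -0.26) and without nonpermissive replicate 1 (-0.52). The median of the p53 list was 0.76 with arrays scaled to the spike-in controls.

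Among 13 CDK inhibitors, D cyclins, cyclin-dependent kinases and members of the Rb family, 8 rose and 1 fell (median log2 change 0.34, adjusted p by camera 0.0035). The adjusted p was 0.283 with an estimated correlation. With arrays scaled to the spike-in controls the median turned to -0.09, with 5 members higher and 2 lower. The list still passed as higher relative to the other genes (adjusted p by camera 0.0052). The rises were not limited to inhibitors of the cell cycle, since Ccnd2, a cyclin that activates CDK4 and CDK6, led the list at 3.32 ± 0.12 (SE). Cdkn1a came next. Cdkn1b (p27) changed by 0.34 ± 0.10 (SE), a call that was lost without nonpermissive replicate 1 (0.25) and with arrays centred on their medians (0.13), and the change turned to -0.11 with arrays scaled to the spike-in controls. Cdk7 had a log2 change of -0.38, and its call was lost when permissive replicate 2 or either nonpermissive array was left out (-0.26 to -0.40).

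Genes of DNA replication and genes of mitosis did not move together. Of 36 replication genes, 18 rose and 5 fell (median log2 change 0.32, adjusted p by camera 0.0035, adjusted p = 0.283 with an estimated correlation). With arrays scaled to the spike-in controls the median was -0.05, with 5 members higher and 7 lower. The camera call was then lost (adjusted p 0.115), while the median of all tested genes was -0.36. This scaling shifts all genes of an array by 1 amount from the deposited scale, where the list passed (adjusted p by camera 0.0091). The list's distance in log2 change from the other genes was the same in both, so the lost call does not show a smaller distance. Thymidylate synthase Tyms and the primase subunit Prim2 rose by 1.35 ± 0.23 and 1.35 ± 0.22 (SE), Tyms from under the limit for dim genes. Cyclin E1, encoded by Ccne1, and the polymerase subunit Pold2 were lower, at -0.83 ± 0.11 and -0.75 ± 0.09 (SE). The sliding clamp Pcna changed by 0.39 ± 0.08 (SE), which became 0.14 with arrays centred on their medians and -0.095 with arrays scaled to the spike-in controls, without a call in either. Of 32 genes of G2 and mitosis, 9 rose and 10 fell, and the list as a whole did not pass (adjusted p by camera 0.613). The counts were 8 higher and 14 lower with arrays centred on their medians and 2 higher and 21 lower with arrays scaled to the spike-in controls, and the list did not pass under these scalings either. The mitotic kinase Plk1 fell by 1.26 ± 0.10 (SE) on the log2 scale and Cdc20, an activator of the anaphase-promoting complex, was at -0.97 ± 0.09. Further Cdc20 probe sets above the limit for dim genes had log2 changes of -1.02, -0.90 and -0.23. Cyclin B1 (Ccnb1) was at -0.94 ± 0.09 (SE), and at -0.54 by a second probe set. In the other direction, Aurkb rose by 1.10 ± 0.14 (SE) and Hmmr by 0.83 ± 0.11. The proliferation marker Mki67 changed by 0.32 ± 0.12 (SE), just past the threshold with an adjusted p of 0.0493. Its call was lost without permissive replicate 1 (0.12) or either nonpermissive array (0.29 and 0.37), on the deposited scale (0.28) and with arrays centred on their medians (0.13), and its change was -0.10 with arrays scaled to the spike-in controls. Top2a changed by 0.16 ± 0.10 (SE) and did not pass, and a second probe set was at -0.11. Of 14 DNA repair and checkpoint genes 5 rose, led by Xrcc1 (1.04) and Brca2 (0.81), and 1 fell, Xrcc5 (-0.97). That list did not pass (adjusted p by camera 0.243) and had 3 higher and 3 lower with arrays scaled to the spike-in controls.

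The list with the most uniform change was that of the nucleolus and ribosome biogenesis, in which all 23 tested members fell (median log2 change -1.09, adjusted p by camera 8.53e-12, adjusted p = 0.257 with an estimated correlation). All 23 were also called lower under each of the other scalings, of which median centring and spike-in scaling lower every gene's change relative to the deposited scale. The 23 include Myc and the metabolic enzymes Odc1, Srm and Cad, and Myc is counted again in the MAX network below. The polyamine enzyme spermidine synthase (Srm) was 3.97-fold lower, from 10.89 ± 0.09 to 8.90 ± 0.01 (SD, n = 2 each), and Nop14, a factor of small ribosomal subunit assembly, was 3.88-fold lower. The ribosomal proteins themselves were at a median of -0.06, with 2 of 27 higher, 5 lower and 20 not called (adjusted p by camera 0.613). On the deposited scale 11 of them were lower and none higher, with arrays centred on their medians 18 were lower, and with arrays scaled to the spike-in controls 25 were lower. The list then passed as lower, with adjusted p by camera of 0.0364, 0.00313 and 0.00335. With an estimated correlation, run after quantile normalization only, its adjusted p was 0.650. The deposited scale, median centring and spike-in scaling differ by 1 shift per array. The distance of the ribosomal protein list from the other genes was thus the same in these.

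Genes of several metabolic pathways fell. In cholesterol biosynthesis 18 of 19 members fell and none rose (median log2 change -0.77, adjusted p by camera 4.85e-08, adjusted p = 0.257 with an estimated correlation). Mvd, which makes isopentenyl pyrophosphate, was 3.88-fold lower and the sterol reductase Tm7sf2 3.08-fold lower. Among 16 genes of glycolysis and hypoxia 12 fell and 1 rose (median -0.51, adjusted p by camera 0.0035, adjusted p = 0.283 with an estimated correlation). Hexokinase Hk2 was at -1.71 ± 0.30, under the limit for dim genes at 39 °C, and the platelet phosphofructokinase Pfkp at -1.41 ± 0.12 (SE). The muscle phosphofructokinase Pfkm was the member called higher (0.46), a call that was lost without permissive replicate 1 (0.40) or nonpermissive replicate 1 (0.29) and with arrays scaled to the spike-in controls (0.18). Of 36 subunits of oxidative phosphorylation 17 fell and 3 rose (median -0.26, adjusted p by camera 0.0107, adjusted p = 0.283 with an estimated correlation). The complex III subunit Uqcrc1 (-1.10) and the complex I subunit Ndufb8 (-1.03) fell furthest. The oxidative phosphorylation counts were 20 lower and 1 higher on the deposited scale, 27 and 1 with arrays centred on their medians and 32 and 0 with arrays scaled to the spike-in controls (median -0.72). The medians of these 3 lists stayed below 0 under every scaling, though median centring and spike-in scaling could only lower them from the deposited scale.

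**Figure D2:**
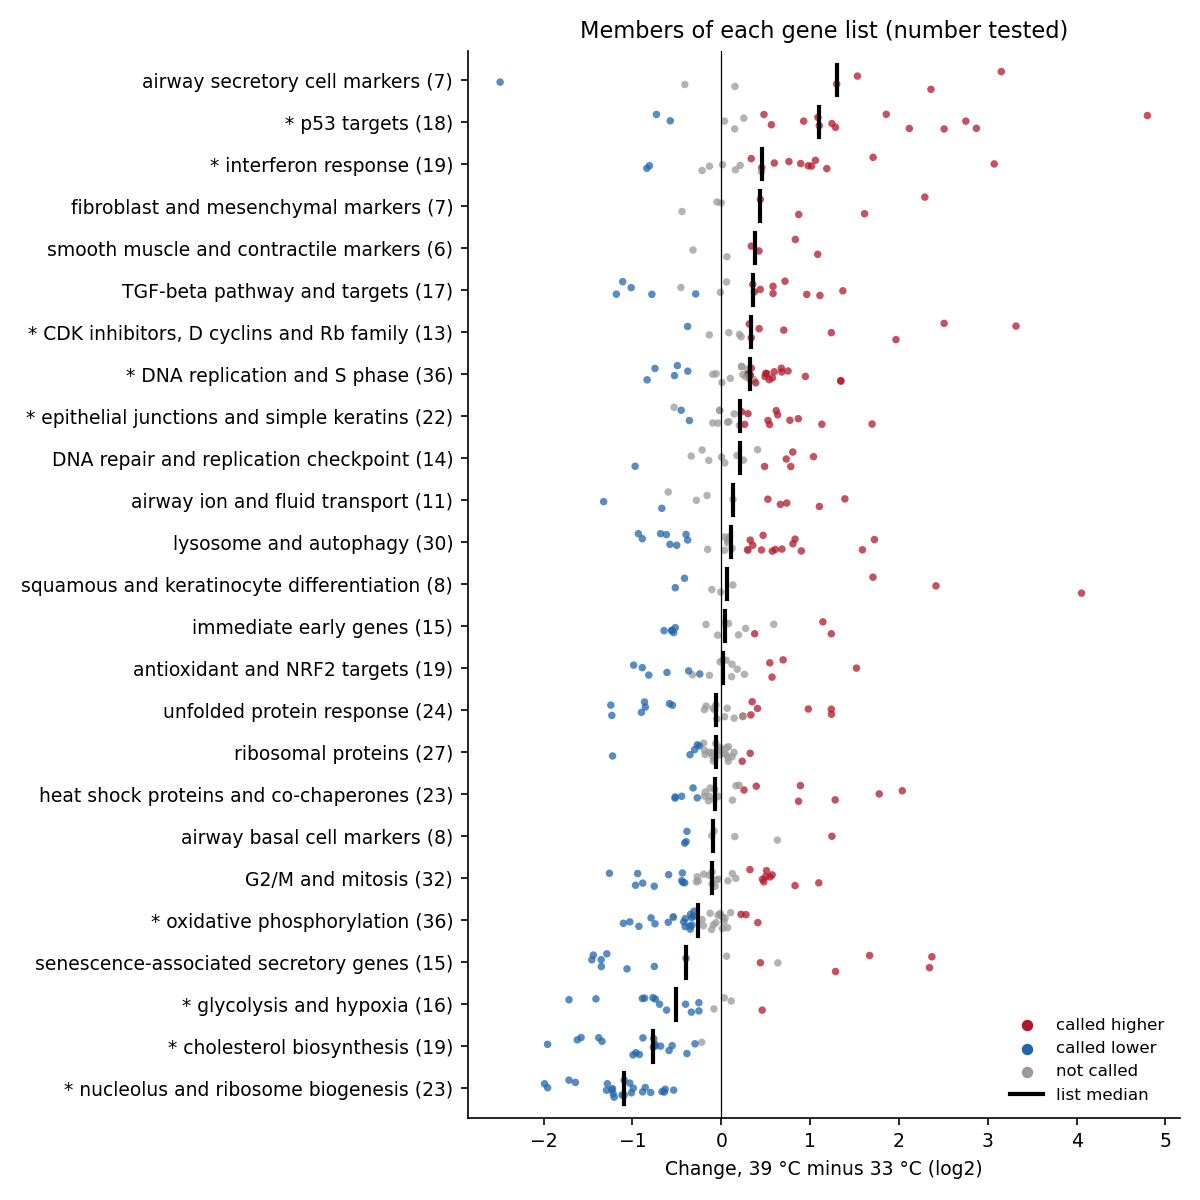
Each row is 1 of the 25 gene lists with at least 5 tested genes, sorted by the median, with the number tested in brackets and an asterisk where camera with the preset correlation gave an adjusted p under 0.05. Points are genes, placed by their log2 change at 39 °C against 33 °C, and black bars are list medians, from 1.30 for airway secretory cell markers to -1.09 for ribosome biogenesis.

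Markers of airway cell types changed in different directions. Of 7 tested markers of airway secretory cells 4 rose and 1 fell (median log2 change 1.30, adjusted p by camera 0.116). The list passed as higher with arrays centred on their medians (adjusted p 0.0472) and with arrays scaled to the spike-in controls (adjusted p 0.0063), and did not pass on the deposited scale (adjusted p 0.127). With an estimated correlation, run after quantile normalization only, its adjusted p was 0.363. The deposited scale, median centring and spike-in scaling differ by 1 shift per array. The list's distance in log2 change from the other genes was the same in these, so the differing calls add no support for a rise. Scgb1a1, the secretory protein of club cells, rose 8.90-fold, from 6.05 ± 0.30, under the limit for dim genes, to 9.20 ± 0.20 (SD, n = 2 each). The retinal dehydrogenase Aldh1a1 rose 5.14-fold and the membrane mucin Muc1 2.46-fold, both from levels under that limit. Lcn2, also in this list, was 5.62-fold lower. Of 8 basal cell markers 1 rose and 3 fell (adjusted p by camera 0.944), against 1 higher and 6 lower with arrays scaled to the spike-in controls. The laminin receptor subunit Itgb4 rose by 1.25 ± 0.09 (SE), while Krt14, a keratin of basal cells, was at 13.60 at 33 °C and 13.52 at 39 °C, a change of -0.08 ± 0.07 (SE, not called). The Krt14 change was called with arrays centred on their medians (-0.28) and with arrays scaled to the spike-in controls (-0.51). Krt5 lay under the limit for dim genes. Of 3 tested ciliated cell markers 2 were lower, Tppp3 (-0.91) and Tubb4b (-0.39). The Tppp3 call was lost without permissive replicate 2 (-0.81) or nonpermissive replicate 2 (-0.51), and the Tubb4b call without nonpermissive replicate 2 (-0.26). Foxj1, the regulator of ciliogenesis, lay under the limit for dim genes.

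Among 8 squamous differentiation genes 3 rose and 2 fell (adjusted p by camera 0.208), against 3 higher and 5 lower with arrays scaled to the spike-in controls. Krt4, a keratin of stratified epithelia, and the desmosomal cadherin Dsc2 led the rises, Dsc2 at 2.42 ± 0.09 (SE). Klf4 was at -0.52 and the transglutaminase Tgm1 at -0.41. Of 22 genes of epithelial junctions and simple keratins 11 rose and 2 fell (median 0.22, adjusted p by camera 0.0138, adjusted p = 0.283 with an estimated correlation). This camera call was lost on the deposited scale (median 0.15, adjusted p 0.0918) and with arrays centred on their medians (median -0.0037, adjusted p 0.169). In both, 8 members were higher and 2 lower. It was lost as well with arrays scaled to the spike-in controls (median -0.24, adjusted p 0.325), where 4 were higher and 9 lower. Median centring and spike-in scaling shift whole arrays from the deposited scale, so the list's distance from the other genes was as on that scale. The epithelial transcription factor Elf3 rose by 1.70 ± 0.15 and desmoplakin (Dsp) by 1.13 ± 0.11 (SE). The simple keratins Krt7 (-0.45) and Krt18 (-0.36) fell, while Krt19 (0.77) and Krt8 (0.23) rose. The Krt8 call was lost on the deposited scale (0.17) and with arrays centred on their medians (0.03). E-cadherin (Cdh1) changed by 0.09 ± 0.08 (SE) and was not called, and its change was -0.0064 on the deposited scale and -0.39 with arrays scaled to the spike-in controls. Of 11 genes of ion and fluid transport 5 rose, led by the bicarbonate cotransporter Slc4a4 (1.39, from under the limit for dim genes, with a second, dim probe set at 0.37) and the potassium channel Kcnq1 (1.11), and 2 fell, Slc4a2 (-1.32) and Fxyd3 (-0.67), with an adjusted p by camera of 0.507. This list had 3 higher and 4 lower with arrays scaled to the spike-in controls.

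Markers of other cell types were mostly dim. None of the 12 endothelial markers on the array passed the limit for dim genes. Of 18 leukocyte markers 3 passed it and none of these was called, though 1 was called lower with arrays centred on their medians and 1 with arrays scaled to the spike-in controls. Of 12 neuroendocrine markers 2 passed it, and Uchl1 was called. Among fibroblast markers 7 of 27 passed it, of which 4 rose and none fell (adjusted p by camera 0.116), led by the collagens Col5a2 (2.29) and Col3a1 (1.61), both from levels under the limit at 33 °C. Vimentin (Vim) and fibronectin (Fn1) changed by -0.0012 ± 0.09 and -0.05 ± 0.08 (SE) and were not called, though both were called lower with arrays centred on their medians (-0.26 and -0.29) and with arrays scaled to the spike-in controls (-0.50 and -0.52). Of 6 tested smooth muscle genes 4 rose (adjusted p by camera 0.116), including Smtn (1.09). Another of the 4 was Tpm1 (0.34), a gene with probe sets called in opposite directions. The medians of the fibroblast and smooth muscle lists, 0.44 and 0.38, were -0.02 and -0.11 with arrays scaled to the spike-in controls. The fibroblast counts were then 3 higher and 3 lower, against 4 and 3 with arrays centred on their medians. For smooth muscle they were 1 higher and 2 lower, against 2 and 0 with arrays centred on their medians.

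Both cold-inducible RNA-binding proteins were lower at 39 °C, Rbm3 as given above and Cirbp at -1.57 ± 0.18 (SE). Heat shock proteins and co-chaperones went both ways, with 7 of 23 higher and 5 lower (adjusted p by camera 0.517). Their median was -0.07 and their mean 0.22, and the median was 0.01 on the deposited scale and -0.37 with arrays scaled to the spike-in controls, where 5 were higher and 13 lower. The small heat shock protein Hspb1 rose by 2.04 ± 0.10 and the inducible Hspa1a by 0.89 ± 0.17 (SE). The 5 lower members were the chaperonin subunits Cct3 and Tcp1 (-0.52 each) and Cct5 (-0.32), with Hspe1 (-0.45) and Hspd1 (-0.27). The split thus depends on which genes the list holds, and these chaperonin subunits are counted again in the cytosolic chaperonin below. In the unfolded protein response 7 of 24 rose and 7 fell (adjusted p by camera 0.828), against 3 higher and 12 lower with arrays centred on their medians and 3 higher and 15 lower with arrays scaled to the spike-in controls. After quantile normalization Dnajb9 and Atf3 were at 1.24 each and Dnajc3 and Asns at -1.24 and -1.23. The chaperone Hspa5 (BiP) changed by -0.19 ± 0.09 (SE) and was not called. It was called lower on the deposited scale (-0.30), with arrays centred on their medians (-0.45) and with arrays scaled to the spike-in controls (-0.68).

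Of 19 interferon response genes 11 rose and 2 fell (median log2 change 0.45, adjusted p by camera 0.0070, adjusted p = 0.345 with an estimated correlation), against 7 higher and 4 lower with arrays scaled to the spike-in controls (median 0.20). The guanylate-binding protein Gbp2 rose by 3.07 ± 0.21, from under the limit for dim genes, and the peptide transporter subunit Tap1 by 1.71 ± 0.18 (SE). Oasl and the immunoproteasome subunit Psmb10 fell, at -0.84 and -0.81. Secreted proteins associated with senescence split, with 5 of 15 higher and 8 lower (adjusted p by camera 0.828). The urokinase Plau rose by 2.37 ± 0.10 and Igfbp7 by 2.34 ± 0.14 (SE), while the cytokine Il1a and the growth factor Vegfa were at -1.46 and -1.44. Of 17 genes of the TGF-beta pathway 9 rose, led by Ltbp1 (1.37) and Tgfb3 (1.11), and 5 fell, including Pmepa1 (-1.18), with an adjusted p by camera of 0.324. With arrays scaled to the spike-in controls 3 of these were higher and 7 lower (median -0.06). Of 19 antioxidant genes 4 rose, with catalase (Cat) at 1.52, and 6 fell, with Sod2 at -0.99 (adjusted p by camera 0.931), against 1 higher and 10 lower with arrays scaled to the spike-in controls. Of 30 lysosomal and autophagy genes 13 rose and 8 fell (adjusted p by camera 0.126), against 6 higher and 15 lower with arrays scaled to the spike-in controls (median -0.23). The lysosomal peptidase Tpp1 (1.72) and the hexosaminidase subunit Hexa (1.59) led the rises, while Cd63 was at -0.93. Of 15 immediate early genes 3 rose, with Jun at 1.14, and 5 fell, with Egr1 at -0.64 (adjusted p by camera 0.944).

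Adjusted over the list alone, 23 replication genes were higher and 5 lower, 12 interferon genes were higher and 2 lower, 4 fibroblast markers were higher and 1 lower, and 1 ciliated cell marker was higher and 2 lower. For the other lists these counts equalled those over all genes. By camera with the preset correlation of 0.01, 9 of the 25 lists passed, 5 higher and 4 lower. With an estimated correlation 0 passed (lowest adjusted p 0.257), and 3 had an unadjusted p under 0.05. That form of camera rests on the 2 residual degrees of freedom and has little power with 4 arrays. For these 3 lists the estimated correlations were -0.05 (p53 targets), -0.02 (cholesterol biosynthesis) and 0.04 (ribosome biogenesis). The lost calls therefore do not show that correlation between genes undoes the list shifts. By fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 21 passed.

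**Figure D3:**
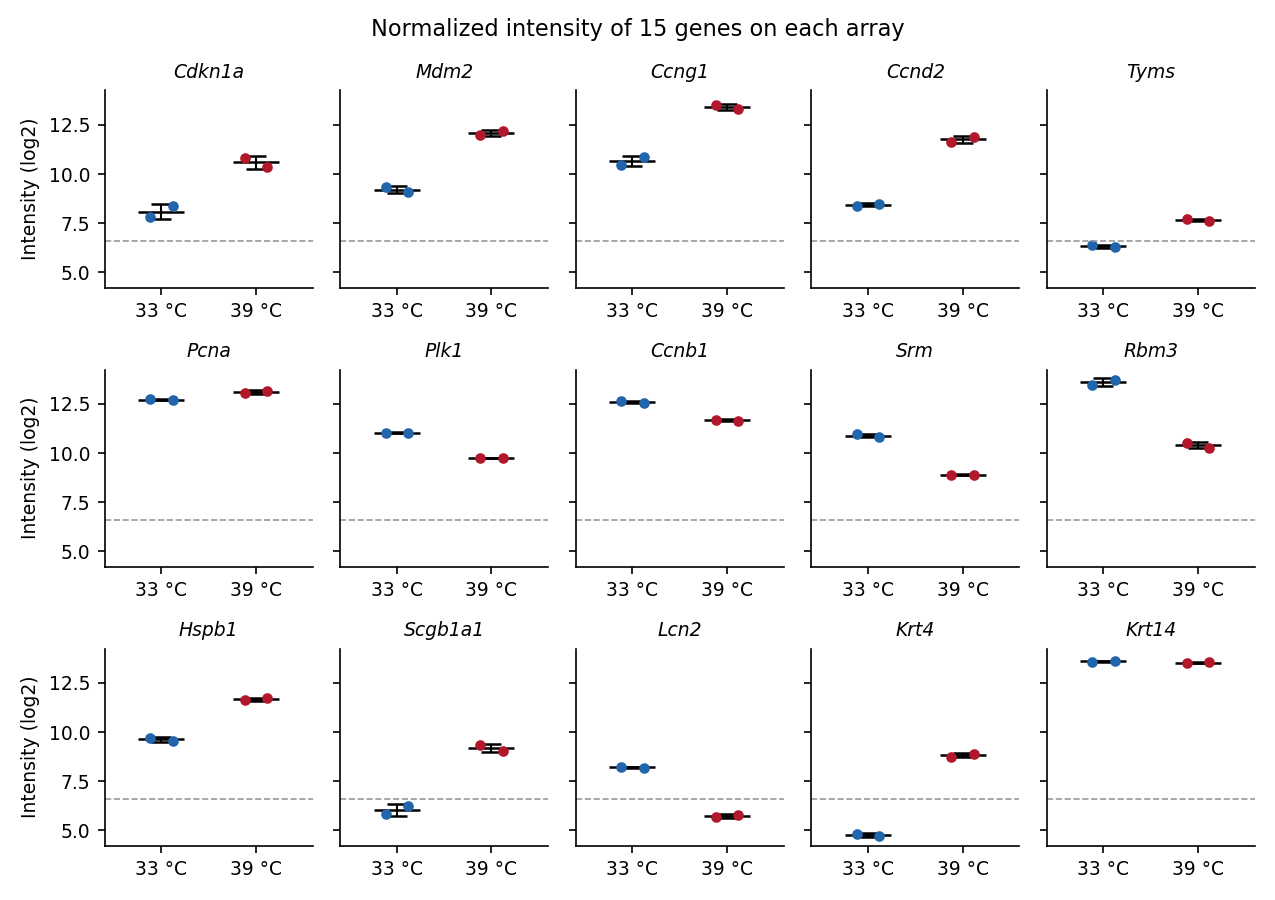
Points are the log2 normalized intensities of named genes on the 2 arrays at 33 °C (blue) and the 2 at 39 °C (red), horizontal bars are means, error bars are SDs (n = 2), and the dashed line is the limit for dim genes at 6.60. Scgb1a1 and Krt4 lie below that line at 33 °C and above it at 39 °C, Lcn2 does the reverse, and Krt14 stays near 13.6 and 13.5.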

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

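All tests in this part were chosen after the result was seen. The poly-A spike-in controls, bacterial transcripts that labelling kits supply for addition to total RNA before cDNA synthesis, were brighter on the nonpermissive arrays. They stand outside the comparison of genes. On the deposited scale their mean log2 intensity over 24 probe sets was 6.63 and 6.69 on the permissive arrays and 6.99 and 7.09 on the nonpermissive arrays, a difference of 0.38 (1.30-fold), with 22 of the 24 probe sets higher at 39 °C. The 4 transcripts gave differences of 0.48 (dap), 0.37 (thr), 0.38 (phe) and 0.29 (lys). Mean levels at 33 °C and 39 °C were 5.87 and 6.25 for phe and 5.85 and 6.14 for lys. These lay under 6.60, the limit for dim genes, while dap and thr lay above it. The log2 scale used understates changes of dim probe sets. The size of the 0.38, and with it the spike-in scaling, thus rests in part on dim values. A larger scaling factor or brighter staining of the nonpermissive arrays is argued against by the hybridisation controls, added after labelling, which differed by -0.0042 over 18 probe sets. A candidate explanation is less polyadenylated RNA in each microgram of total RNA at 39 °C, which would raise the controls relative to the cells' own transcripts by one factor. A larger amount of control added to the nonpermissive samples would give the same difference of 0.38, and the labels do not state the amounts, so these cannot be told apart. If the controls were added in equal amounts, the median change of the tested genes per microgram of total RNA was -0.36 in place of the -0.04 of the quantile normalized arrays. The ratios of 3' to 5' probe sets, a sign of RNA quality, were 1.18 and 1.33 at 33 °C and 1.38 and 1.26 at 39 °C for beta-actin, and 1.17, 1.14, 1.12 and 1.01 for GAPDH in the same order.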

How the results depend on the processing

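The alternatives without genes represented by _x_at or _s_at probe sets and with arrays scaled to the spike-in controls were chosen after seeing the data. The count of genes changed, 3448, lay between 2639 and 4159 under the alternatives that count genes, and 4494 of 9520 probe sets were called without collapsing to genes. Of the calls, 3170 kept their direction and call on the deposited scale, 3167 with median centring and 2626 with spike-in scaling. In the same order, 0, 5 and 166 were called in the opposite direction. Spike-in scaling moved the genes called higher to 800 and those called lower to 3359. It shifts every gene by 1 amount per array, which moves the log2 changes and also alters the spread within groups. Mgmt was at 5.31 on the deposited scale (adjusted p by limma 5.99e-09) and at 4.93 with spike-in scaling (1.61e-15). The counts thus do not follow from the moved log2 changes alone. Leaving out 1 array gave 2639 to 3208 genes, a fit in which the lone array of its group is assumed to vary like the pair. The genes changed at least 2-fold, 764, were 506 with the 60th percentile filter, which tests 5009 genes, and 576 to 1089 otherwise. The gene lists called were 0 with an estimated correlation, 21 with fry and 9 to 11 otherwise. The replicate numbers pair nothing that the data show: same-numbered arrays deviated from their group means with a correlation of -0.006 over genes, from only 2 pairs. With the replicate block 3706 genes were called (1737 higher, 1969 lower) and 11 lists. Of the values of named genes under these alternatives, 1686 kept direction and side of the threshold, 82 lost and 9 gained the call and 13 reversed. Cdh1 was at -0.0064 on the deposited scale, -0.16 with median centring and -0.39 with spike-in scaling. Vim ranged from -0.10 to 0.087 without 1 array. With spike-in scaling Rps29 was at -0.23, Rpl19 at -0.23, Sdhd at -0.16, Cdkn1b at -0.11, Mki67 at -0.10, Pcna at -0.095, Top2a at -0.22 and Krt8 at -0.21. Lists whose direction by camera turned had not been called in any of these settings. Immediate early genes had medians of 0.061 on the deposited scale, -0.088 with median centring, -0.11 with the 60th percentile filter, -0.042 with mean probe sets and without _x_at or _s_at genes, -0.32 with spike-in scaling and -0.025 to 0.068 without 1 array. Airway basal markers had 0.036 with no filter, -0.094 with mean probe sets, with the replicate block and with fry, and -0.15 to -0.039 without 1 array. Senescence-associated secretory genes had 0.44 with the 60th percentile filter, -0.40 with the replicate block, 0.060 without _x_at or _s_at genes, -0.72 with spike-in scaling and -0.46 to -0.14 without 1 array. The cause of these turns was not tested. Signal over background limits genes near the dim limit, whose levels on the dim side carry no detection call.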

Other observations

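The families of amino acid supply, protein synthesis and turnover and the MAX network were chosen after the data were seen. Their counts and p-values are thus not independent evidence of their direction. Their camera p-values were adjusted over these families alone and cannot be set beside those of the 25 lists fixed before. The replication, mitotic, ribosome biogenesis and ribosomal protein lists were fixed before, as were the deposited scale and median centring, while spike-in scaling and the tests that weigh explanations were chosen after. Genes that supply amino acids and charge them to tRNA fell together with the large fall of Slc7a5, which is itself among the transporters below. Of 19 aminoacyl-tRNA synthetases 18 fell and 1 rose (median log2 change -0.92, adjusted p by camera 5.66e-08, adjusted p = 0.0920 with an estimated correlation). The valine enzyme Vars1 was 3.16-fold lower and the tyrosine enzyme Yars1 2.27-fold lower, while the glutamine enzyme Qars1 was 1.66-fold higher, a change no longer called with arrays scaled to the spike-in controls. In serine, glycine and one-carbon metabolism 12 of 13 fell and none rose (median -1.36, adjusted p by camera 5.66e-08, adjusted p = 0.0920 with an estimated correlation). All 3 enzymes of serine synthesis were among them: Phgdh was 3.54-fold lower, Psat1 3.16-fold and Psph 4.42-fold. Of 9 amino acid transporters 8 fell and 1, Slc38a2 (0.35), rose, though no member was called higher with arrays centred on their medians or scaled to the spike-in controls (median -0.73, adjusted p by camera 0.00088, adjusted p = 0.0936 with an estimated correlation).

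Most members of the proteasome, the translation initiation factors and the cytosolic chaperonin were lower as well. Of 27 proteasome subunits 25 fell and none rose (median log2 change -0.60, adjusted p by camera 3.13e-09, adjusted p = 0.0920 with an estimated correlation), with Psmc5 furthest at -1.22. Of 32 translation initiation factors 20 fell and 2 rose (median -0.47, adjusted p by camera 2.56e-05, adjusted p = 0.0920 with an estimated correlation). The risers were the helicase Eif4a2 at 1.32 and its cofactor Eif4b at 0.97, while the helicase Eif4a1 was at -0.49. Of the 8 subunits of the cytosolic chaperonin 6 fell and none rose (median -0.52, adjusted p by camera 0.00087, adjusted p = 0.0936 with an estimated correlation). Cct8 stood apart at -2.52 where the other 7 lay between -0.18 and -0.74. The list medians of these families, and of those of amino acid supply, stayed below 0 under all 4 scalings. Median centring and spike-in scaling could only lower them from the deposited scale. In the network of MAX, the partner of the growth regulator MYC, 3 of 9 rose and 1 fell, and the list did not pass (adjusted p by camera 0.238). The counts were 2 higher and 2 lower with arrays centred on their medians and 2 higher and 3 lower with arrays scaled to the spike-in controls. The MYC antagonists Mxd4 and Mxi1 rose by 2.33 and 1.24 on the log2 scale, and Myc itself was at -0.54.

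Replication genes rose while mitotic genes went both ways after quantile normalization. With spike-in scaling 5 replication genes were higher and 7 lower, and 2 mitotic genes were higher and 21 lower. Chance assignment of genes to these lists is argued against, since the gap between the list medians, 0.43, was reached in a share of 0.0012 of 10000 random reassignments of the same genes (permutation test, two-sided), which treats genes as independent. Scaling stays open for the rise itself: the replication median was 0.32, 0.34 and 0.19 after quantile normalization, on the deposited scale and with median centring, and -0.046 with arrays scaled to the spike-in controls. The gap was 0.43 to 0.47 under these scalings, of which those that shift whole arrays cannot alter it. Fewer cells in mitosis at 39 °C may lower mitotic transcripts and not those of S phase, and 10 of the 32 mitotic genes were called lower and 9 higher after quantile normalization. No cells were counted by phase and these counts depend on the scaling, so this cannot be told apart from a change of transcription in each cell.

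Ribosome biogenesis genes fell further than ribosomal protein genes. The highest median of the biogenesis list under the 4 scalings was -1.09, and all 23 members were called lower in each. Median centring and spike-in scaling lower every gene's change relative to the deposited scale, so neither could have undone the fall. The scalings tried therefore do not decide whether scaling explains it. The gap to the ribosomal protein median was -1.03 after quantile normalization and -0.95 otherwise. This gap does not decide it either, since scalings that shift whole arrays cannot alter it. A fall of genes of this brightness in general is argued against. Among 10000 random lists matched on brightness none had as low a median, a share of 0.0001, the smallest these draws can give. The lowest random median was -0.57. Saturation of bright probe sets could hide a fall of the ribosomal proteins. Of 9 other genes as bright, 11.1% changed by 0.5 or more on the log2 scale, by a rise, and the largest fall was -0.39. Such values leave saturation open, and 9 genes are too few to decide. The temperature itself and the loss of antigen activity both stay open as biological explanations, and the design could not separate them.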
